A study of Mus musculus with 12 samples.

How the data were processed

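Poly(A) RNA libraries of mouse embryonic fibroblasts null for Myod1 and Myf5 were read from 2 gene count tables. Per the submitters' processing notes, base calls came from CASAVA 1.8.2 and reads were aligned to mm9 with TopHat2 2.0.8. How reads were counted per gene, and with which annotation release, is not given in the sources used here. The first table, as deposited, holds expected counts that are not whole for 1982 to 2767 genes per library (14.6% to 22.2% of the counts, tolerance 1e-06), and they were rounded to whole numbers. The second table holds whole-number counts as deposited. Both list 37287 gene IDs. Of these, 32610 were paired with symbols such as Myod1 and Myf5 through the GENCODE vM21 names, and 1.26% to 1.45% of a library's counts lay in IDs without a symbol. Because that annotation is of another build than mm9, no positions are given. The 37 mitochondrial genes have no count in the first table and take 4.05% and 4.18% of the second, so the tables were not fitted together. Where Chimera was set against first-batch MyoD of the other table, these genes were left out of the totals, and differences in processing between the tables remain in the values.

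Groups were taken from the labels: GFP (5 libraries, of which 4 form an MOI series), MyoD (2), Myf5 (2), untransduced (1), Chimera (1) and MyoD of a second virus batch (1). Total counts, in M (mega), were 19.7, 17.9, 22.4 and 20.1 M at an MOI of 15, 30, 60 and 120, 81.5 M for 1x GFP, 80.6 and 76.8 M for 1x and 2x MyoD, 68.3 and 68.5 M for 1x and 2x Myf5, 72.7 M without virus, 25.1 M for Chimera and 23.7 M for second-batch MyoD. Libraries of a group differed beyond counting noise (chi-square per degree of freedom of 1.93 to 137), so none is a copy of another.

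In R 4.3.3, edgeR 4.0.16 fitted the first table with TMM normalization to genes with a CPM of at least 1 in at least 2 libraries. The quasi-likelihood test (two-sided, Benjamini-Hochberg adjusted p under 0.05) compared MyoD, Myf5 and the untransduced library with GFP and MyoD with Myf5 over 13825 genes at 6 residual degrees of freedom. A common effect of 2x over 1x dose was fitted within both factors, and a slope on log2 MOI was fitted over 13383 genes in the 4 MOI libraries. The biological coefficient of variation was 0.157 over the groups, where it holds dose differences within a group, and 0.0303 along the MOI series. Groups of 1 library were assumed to vary like the others. Gene-wise standard errors were derived from the quasi-likelihood F statistic. Values against 1x GFP alone came from a fit with the MOI libraries as a group of their own. Where Ckm or Hfe2 had no count in a group, a floor of 3 counts over the group gave a lower bound, and ratios from 1 to 3 counts carry 95% counting intervals, which cover counting error only.

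The 22 gene lists, such as sarcomere genes (Actc1, Ttn) or interferon-stimulated genes (Ifit2, Rsad2), were written before the data were examined, as were the comparisons, the main test, the filters and the rule for naming genes. None of the 10 epithelial genes passed the filter, so 21 lists were tested. Of the genes written, 1 of 18 cholesterol genes and 1 of 14 macrophage genes matched no symbol, and 3 genes sit in more than 1 list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry. Fry tests whether the genes of a list move, on balance, 1 way and does not set them against other genes. Over MyoD against GFP, Myf5 against GFP, MyoD against Myf5, untransduced against GFP, the MOI trend and the dose effect, preset camera called 12, 11, 10, 2, 5 and 9 lists, camera with an estimated correlation 0, 0, 0, 0, 0 and 2, and fry 10, 8, 5, 1, 2 and 6. Genes were named by rule: Myod1, Myf5 and Myog, then the 8 largest rises and falls per direction in the comparisons of MyoD, Myf5 and GFP, 5 in the untransduced, MOI and dose comparisons, 10 for Chimera, each with a mean CPM of at least 5 or at least 50 counts, and the 2 members with the smallest p of each called list. The largest changes also had to be called and to separate every library of 1 group from every library of the other, to be monotone in MOI for the trend, or to go the same way with both factors for dose. Other list members, such as Ryr1, Mymx and Lum, were chosen after their values were seen. Some genes that the rule names are not reported here.

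Chimera and second-batch MyoD were compared by ratios of CPM with exact 95% binomial intervals over 13412 genes with at least 50 counts, with a prior count of 2 for log2 ratios. List medians were set against 10000 random lists matched on size and on 20 bins of expression, which do not keep the correlation between genes of a list. The 95% intervals of list medians came from the ranked ratios of the genes, taken as independent. The shared response to MyoD and Myf5 was set against 40 simulated draws of unchanged groups and against the overlap of independent lists.

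The 6 gene-wise comparisons and the counting intervals were tested on simulated counts, the former with 100 genes changed at each size. The list tests, random lists and dose interaction were not. All simulated libraries of a comparison were drawn around 1 baseline, with a spread set by expression level alone. They held no gene-specific spread and no shift of the MOI libraries from 1x GFP, so recovery in these data can be lower. Of 2-fold changes 86% were recovered for MyoD against GFP (13598 genes), 83% for Myf5 against GFP (13610), 78% for MyoD against Myf5 (13594), 72% for untransduced against GFP (13581) and 77% for dose (13607). Of 4-fold changes 97% to 100% were recovered. Of 1.1-fold changes per 2-fold MOI 50% and of 1.5-fold changes 99% were recovered (13290 genes). Between 6 and 13 unchanged genes were called, and 95.1% of the counting intervals held the ratio set.

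Alternatives were DESeq2 size factors, no filter, a CPM of at least 5, DESeq2 1.42.0, limma-voom, each library left out, dose as a term, other control sets, linear MOI, the untransduced library as dose 0, other prior counts and count minimums, and TMM for Chimera. Restricting the fit to the 6 deeper libraries, giving the MOI libraries their own group, leaving mitochondrial genes out, setting Chimera list medians against first-batch MyoD and counting list genes that reach the filter in GFP libraries were chosen after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9. No per-sample column was left unused.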

Results

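Poly(A) RNA was sequenced from mouse embryonic fibroblasts labelled as null for Myod1 and Myf5, the genes of the muscle-determining transcription factors MyoD and Myf5. The cells were transduced with lentivirus, moved to differentiation medium and harvested 20 h later, so that each library reports the early response to 1 introduced factor. The first table held 10 libraries: 5 with a GFP virus, 2 with MyoD, 2 with Myf5 and 1 that received no virus. Of the GFP libraries, 4 formed a series of multiplicity of infection (MOI) of 15, 30, 60 and 120, and 1 was made at the 1x dose that the MyoD and Myf5 viruses share. MyoD and Myf5 each had 1 library at the 1x dose and 1 at the 2x dose. The second table held 1 library with a virus labelled Chimera and 1 with MyoD from a second virus batch. The makeup of the Chimera protein is not given in the sources used here. The 4 MOI libraries held 17.9 to 22.4 M counts (M, mega) and the other 6 libraries of that set held 68.3 to 81.5 M. Chimera held 25.1 M and second-batch MyoD 23.7 M. Because the MOI libraries also differed from the 1x GFP library in 3369 genes (1677 higher, 1692 lower, edgeR quasi-likelihood test, adjusted p under 0.05), values against the 1x GFP library alone stand beside those against all 5 GFP libraries. Libraries of a group are labelled with different viral doses, so the p-values measure a spread between these libraries that holds dose as well. How 1x relates to the MOI series is not given, and nothing in the labels says that any dose was repeated in a second culture.

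The introduced factors were read out first, as a check on the labels. Myod1 (ENSMUSG00000009471.3) stood at 309 CPM (counts per M counts of the library) in 1x MyoD and 617 CPM in 2x MyoD, against 5.71 ± 0.24 CPM (SD, n = 5) with GFP, 5.31 CPM without virus and 5.29 ± 0.10 CPM (SD, n = 2) with Myf5. Myf5 (ENSMUSG00000000435.1) stood at 149.5 CPM in 1x Myf5 and 249 CPM in 2x Myf5, against 18.7 ± 1.5 CPM (SD, n = 5) with GFP, 24.4 CPM without virus and 13.4 ± 2.2 CPM (SD, n = 2) with MyoD. The reads of both genes in libraries without their virus stand against the null label unless they come from what the null alleles still transcribe, which counts per gene cannot show. Myog (ENSMUSG00000026459.4), the muscle-specific factor that acts after both in muscle differentiation, reached 270.3 CPM in 1x MyoD and 763 CPM in 2x MyoD, but 5.92 CPM in 1x Myf5 and 29.4 CPM in 2x Myf5. Myog had no count in the 4 MOI GFP libraries and stood at 0.503 CPM in 1x GFP and 0.248 CPM without virus. In the second table, Myod1 stood at 324 CPM and Myf5 at 14.7 CPM in the second-batch MyoD library, while the Chimera library held 22.1 CPM of Myod1, 165 CPM of Myf5 and 300.3 CPM of Myog. The tables were made separately, so levels set across them are descriptive.

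**Figure D1:**
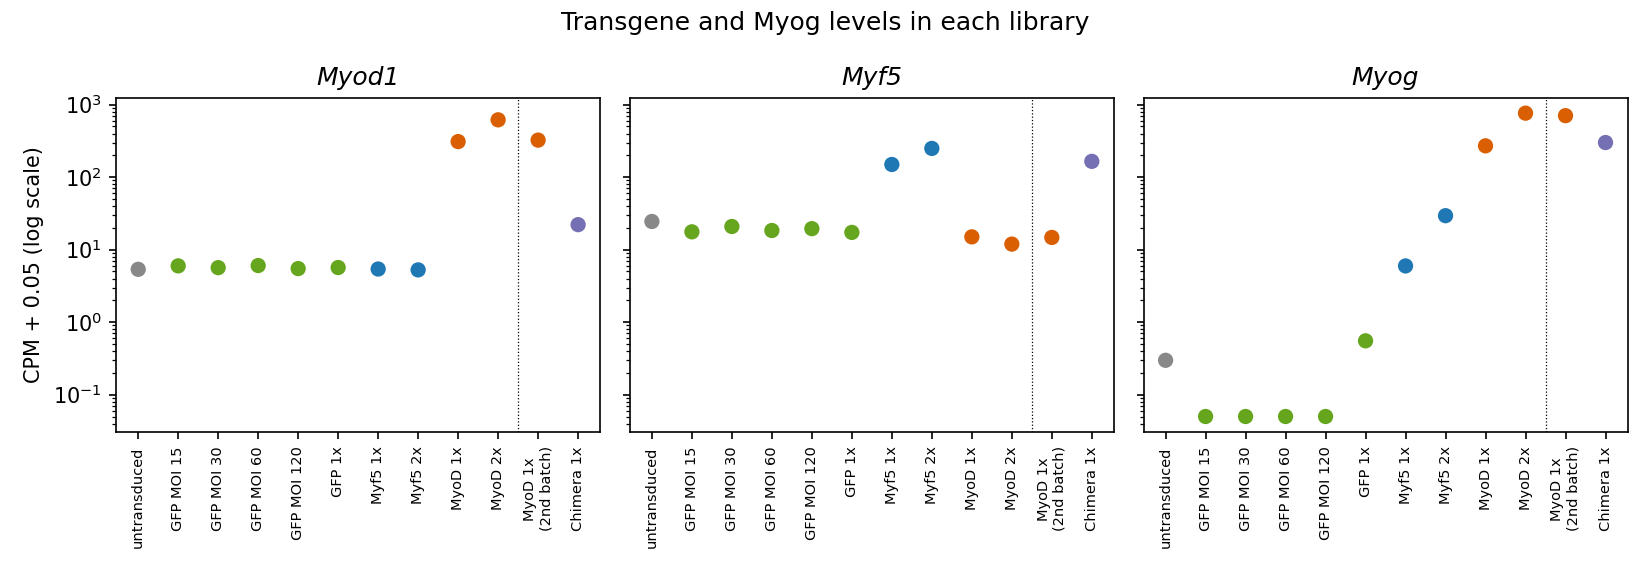
CPM plus 0.05, on a log axis, of Myod1, Myf5 and Myog in each of the 12 libraries, 1 point per library, with a dotted line between the first and the second table. Myod1 is at 309 CPM or more only in the 3 MyoD libraries, Myf5 is at 149.5 CPM or more only in both Myf5 libraries and in Chimera, and Myog is highest in 2x MyoD at 763 CPM.

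MyoD against GFP asks which transcripts change when MyoD is expressed in these fibroblasts. Of 50 sarcomere genes written, 29 reached the count filter, which the MyoD libraries alone can meet, and 28 of these rose (29 adjusted over the list alone). In the GFP libraries alone 12 reached it, and 11 of them rose (median log2 fold change 2.46). Genes that rose included Actc1, an actin of heart and embryonic skeletal muscle (log2 fold change 10.82 ± 0.87, SE), the troponin Tnnt2 (8.74 ± 0.63) and Smyd1, a methyltransferase of developing muscle (7.53 ± 0.52), while Myom1 was at 0.68. Genes of the neuromuscular junction and of excitation-contraction coupling followed. Here 19 of 20 members were higher (20 adjusted over the list alone, and 9 of the 10 that reached the filter in GFP libraries), including Chrng, the fetal gamma subunit of the acetylcholine receptor (7.37 ± 0.28), Rapsn, which clusters that receptor (6.31 ± 0.28), and Ryr1, the calcium release channel of skeletal muscle (7.73). Of the myogenic transcription factors and cofactors 12 of 16 rose, led by Myog (11.16 ± 0.88), with Rbm24 at 10.26 and Eya4 at 2.94 ± 0.20. The Rbm24 value rests on 4 counts in 1x GFP and none in the MOI libraries. Of the muscle energy genes 11 of 13 rose, among them Cox8b (7.84 ± 0.47), Pgam2 (2.39 ± 0.28) and the muscle creatine kinase Ckm. The fusion and adhesion list split, since the fusogens Mymk (11.70 ± 0.77) and Mymx (7.87), the cadherin Cdh15 (10.81 ± 0.51), Itga7 (3.38 ± 0.21) and 3 others rose, whereas Cdon and Igsf8 fell by 0.43 and 0.48 on the log2 scale. Adjusted over the list alone, 12 transcription factors, 11 energy genes and 7 fusion genes rose and 3 fusion genes fell.

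Ckm and Hfe2, the hemojuvelin gene, had no count in any GFP library, and against a floor of 3 counts over that group they were at least 962-fold and at least 1055.5-fold higher. Asb2, part of a muscle ubiquitin ligase, and the myosin-binding gene Mybph had 2 counts each over the 5 GFP libraries. Their ratios were 2222-fold (95% counting interval 615 to 18351) and 1909-fold (528 to 15766). By camera with a preset correlation, which sets a list against the remaining genes, the sarcomere list stood higher at an adjusted p of 5.5e-17 (median log2 fold change 6.45), the neuromuscular list at 2.3e-13 (5.27), the energy list at 9.6e-06 (2.15) and the transcription factor list at 3.1e-07 (1.52). For each of these 4 lists, camera gave adjusted p = 0.211 with an estimated correlation. The fusion list had a median of 0.44, an adjusted p of 0.0168 and adjusted p = 0.239 with an estimated correlation. The energy list's median stayed at 2.15 with Ckm at its bound. Over genes that reached the filter in the GFP libraries alone, medians were lower, at 2.17 for 10 neuromuscular genes, 0.49 for 8 energy genes (6 rose), 1.05 for 13 transcription factors (9 rose) and 0.13 for 10 fusion genes (4 rose, 2 fell).

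Among genes of other cell states, 7 of 11 genes of the list of Notch and Id targets rose (8 adjusted over the list alone). They included the receptors Notch3 at 3.02 ± 0.17 and Notch1 at 2.52 ± 0.16 and the ligand Dll1 at 4.13 (camera adjusted p = 7.3e-05, and adjusted p = 0.211 with an estimated correlation). Because the list holds such receptors and a ligand as well, its rise is not that of targets alone. Of 9 smooth muscle and myofibroblast genes, 7 rose, among them Ckb (2.25 ± 0.26) and Synpo2 (2.08 ± 0.28), and Itga8 fell by 0.64. The counts were the same adjusted over the list alone (camera adjusted p = 0.00401, and adjusted p = 0.265 with an estimated correlation). Against 1x GFP that camera value was 0.0583. Of fibroblast and extracellular matrix genes 19 of 28 fell, also when adjusted over the list alone, and none rose. Among them were the small proteoglycan Lum at -2.32, the collagen Col6a1 at -1.02 ± 0.15 and the crosslinking enzyme Lox at -1.34 ± 0.20. That list's median was -0.62 (camera adjusted p = 5.9e-07, and adjusted p = 0.265 with an estimated correlation). In the unfolded protein and integrated stress list 10 of 17 genes fell, including Ddit3 (-1.24 ± 0.18). Psat1 (0.84) and Edem1 (0.20) rose (camera adjusted p = 0.00385, and adjusted p = 0.211 with an estimated correlation). Adjusted over the list alone, 11 stress genes fell and 2 rose. All 3 measured chondrocyte and osteoblast genes fell, also when adjusted over the list alone. They were Col11a1 at -1.43, Runx2 at -0.79 ± 0.11 and Sox9 at -0.72 ± 0.19 (camera adjusted p = 0.0467, and adjusted p = 0.267 with an estimated correlation, but 0.137 by preset camera against 1x GFP). The cell cycle list had 5 of 34 genes up and 5 down (median 0.05), and p53 targets had 7 of 17 up, among them Cdkn1a (1.34) and Btg2 (1.33), and 2 down (0.08). Pitx3, with 1 to 3 counts over the GFP libraries, and Met (1.25) rose and Pax3 (-0.22) fell among 7 progenitor genes (0.01), and 1 of 18 serum response genes rose and 4 fell (-0.18). Of the lists for other lineages, 1 of 4 cardiac genes fell (-0.24), 1 of 5 adipocyte genes rose (-0.41), 1 endothelial gene of 4, Vwf (1.94), rose and 1 fell (-0.12), 1 of 5 macrophage genes rose (-0.31) and 2 of 6 neuron and glia genes, Map2 (1.48) and Tubb3 (1.15), rose and 2 fell. None of these 9 lists passed camera against all GFP libraries, and the endothelial, macrophage and neuron lists had means of 0.21, 0.09 and 0.08, so their median, mean and direction of test differed in sign. Against 1x GFP 11 of 18 serum response genes fell and 1 rose (12 and 1 adjusted over the list alone). That list's median was then -0.69 (camera adjusted p = 0.00029, and adjusted p = 0.342 with an estimated correlation).

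The direction of the interferon-stimulated list depended on the control, as did the sign of the median in the cholesterol, cell cycle, cardiac, progenitor and neuron lists (cell cycle at -0.26 against 1x GFP). Against all 5 GFP libraries 16 of 30 fell (26 adjusted over the list alone), with Gbp2 at -2.58 ± 0.69 and Ifit2 at -1.94 ± 0.56. The list median was -2.85 (camera adjusted p = 0.000425, and adjusted p = 0.798 with an estimated correlation). Against the 1x GFP library the list median was 0.62, Gbp2 was at -0.50 and no member was called. The interferon-inducible genes Slfn2 (-3.96 ± 1.23), Gm12185 (-3.91 ± 1.21), Ifi209 (-3.07 ± 0.93) and Ifi207 (-3.06 ± 0.96) were among the 8 largest falls. Against the 1x GFP library they stood at -0.33, -0.35, -0.56 and -0.50, uncalled. Apod went from -3.29 ± 0.84 to -0.71 in the same way. The epithelial factor gene Bnc1 (-3.90 ± 0.56), the retinol receptor gene Stra6 (-3.14 ± 0.51) and Kera, which encodes a matrix proteoglycan (-3.02 ± 0.54), fell with either control. They were at -2.34, -2.27 and -1.62 against 1x GFP. Of 17 cholesterol synthesis genes 3 rose against all GFP libraries, among them Insig1 (0.79 ± 0.15) and Fdft1 (0.60 ± 0.14). Adjusted over the list alone 2 did so (camera adjusted p = 0.0467, and adjusted p = 0.892 with an estimated correlation). None rose against 1x GFP, where the list median was -0.041.

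Over all 13825 genes tested, 2960 were higher and 2896 lower in MyoD than in the 5 GFP libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 701 and 631 changed at least 2-fold. Against the 1x GFP library alone, with the spread pooled over the other groups, 2091 were higher and 2132 lower. Of the genes called against all 5, 90 had the opposite sign against 1x GFP, called there or not. A fit to the 6 deeper libraries alone had 2 residual degrees of freedom, both from 1x against 2x of MyoD and of Myf5. Dose therefore counted as spread in that fit, so its lack of calls does not tell whether the response holds at like depth. Without the 2x MyoD library the total fell to 1833.

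Myf5 against GFP asked the same of Myf5, which raised many of the same muscle genes by smaller amounts. Acetylcholine receptor subunits were among the largest rises, with Chrnd at 7.20 ± 0.41, Chrng at 6.01 ± 0.27 and Chrnb1 at 2.85 ± 0.23 on the log2 scale. With Rapsn (5.03 ± 0.28) they were among 12 of 20 neuromuscular genes that rose (13 adjusted over the list alone). The fusion genes Cdh15 (7.87 ± 0.53), Mymk (7.68), Mymx (5.15), Itga7 (2.67 ± 0.21) and Cdh2 (0.36) rose and Cdon fell by 0.35, and adjusted over the list alone 6 rose and 2 fell. Of 16 transcription factor and cofactor genes 7 rose (11 adjusted over the list alone), among them Myog (6.26 ± 0.90), Rbm24 (5.95) and Eya4 (2.24 ± 0.20). Here too Rbm24 rests on 4 control counts, all in 1x GFP. In the sarcomere list 14 of 29 rose (20 adjusted over the list alone, and 2 of the 12 that reached the filter in GFP libraries), with Tnnt3 at 4.57 ± 0.65 and Tnnt1 at 3.93 ± 0.53, and Ttn, the giant spring protein of the sarcomere, did not pass at 2.21. Against 1x GFP, edgeR called 5 of 20 neuromuscular, 2 of 13 fusion, 1 of 16 transcription factor and 1 of 29 sarcomere genes. In these lists 13, 6, 4 and 11 rose adjusted over the list alone, and 1 fusion gene fell. Myog was then at 5.12 and Tnnt3 at 5.21, both uncalled.

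The camera test gave an adjusted p of 7.1e-11 for the sarcomere list (median 2.72), 7.2e-11 for the neuromuscular list (2.73), 9.0e-07 for the transcription factors (0.43) and 0.00496 for the fusion list (0.21). The sarcomere list then had adjusted p = 0.346 with an estimated correlation, and the other 3 lists had adjusted p = 0.24 with an estimated correlation. Over genes that reached the filter in the GFP libraries alone, the medians were 0.57 for 12 sarcomere genes, 0.52 for 10 neuromuscular genes (4 rose), 0.42 for 13 transcription factors (4 rose) and 0.12 for 10 fusion genes (2 rose, 1 fell). Energy genes rose in 3 of 13 cases, Cox8b (5.31 ± 0.51), Eno3 (1.73) and Ak1 (0.48 ± 0.08), and in 6 adjusted over the list alone (camera adjusted p = 0.006, and adjusted p = 0.357 with an estimated correlation). Of 11 genes of the Notch and Id list, Notch3 (2.09 ± 0.17), Dll1 (1.71), Id2 (0.99) and Notch2 (0.38 ± 0.06) rose and the Notch target Hes1 fell by 0.83. In this list 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.24 with an estimated correlation). Of 17 p53 targets, Plk2 (0.81 ± 0.11), Phlda3 (0.55 ± 0.08) and Bax (0.41) rose, and 6 targets rose adjusted over the list alone (camera adjusted p = 0.000537, and adjusted p = 0.24 with an estimated correlation). Matrix genes fell in 7 of 28 cases, with Lum at -1.96, Col6a2 at -1.08 ± 0.18 and Col6a1 at -0.90 ± 0.15. A total of 10 fell adjusted over the list alone (camera adjusted p = 8.8e-05, and adjusted p = 0.357 with an estimated correlation). Of 34 cell cycle genes 2 rose, Mcm7 (0.40 ± 0.07) and Ccne1 (0.89 ± 0.17), also adjusted over the list alone (camera adjusted p = 0.00496, and adjusted p = 0.585 with an estimated correlation). Synpo2 (1.27 ± 0.29) was the 1 smooth muscle gene of 9 called on either scale (camera adjusted p = 0.0264, and adjusted p = 0.357 with an estimated correlation). Of the 17 stress genes, Xbp1 (-0.29 ± 0.06) and Slc7a11 (-0.47 ± 0.12) fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.278 with an estimated correlation). Against 1x GFP the cell cycle median turned to -0.022 and the smooth muscle median was 0.064, with a camera adjusted p of 0.679 for each. Mcm7 (0.25), Ccne1 (0.64) and Synpo2 (0.79) were not called there. Over all genes, 1 of 13 energy genes, 2 of 11 Notch and Id targets and 2 of 17 p53 targets rose against 1x GFP (4, 5 and 8 adjusted over the list alone). No matrix or stress gene fell there by edgeR over all genes, and 6 and 7 did adjusted over the list alone.

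Outside the lists, the transcription factor gene Mycl rose (4.65 ± 0.32, and 5.26 against 1x GFP) and Gm45837 rose against all GFP libraries (3.38 ± 0.65, and 2.12 uncalled against 1x GFP). Bnc1 (-3.07 ± 0.53), Clec3b (-3.00 ± 0.63), Stra6 (-2.95 ± 0.50), Kera (-2.63 ± 0.53), the unnamed gene ENSMUSG00000087304 (-2.56 ± 0.53), Mmp12 (-2.40 ± 0.46), Tenm4 (-2.35 ± 0.48) and Prelp (-2.02 ± 0.33) were the largest falls. Against 1x GFP only Bnc1 among these 8 was called, at -1.51. No interferon-stimulated gene was called against all 5 GFP libraries by edgeR (list median -0.31). Against 1x GFP the list median was 3.13 and 1 member was called, or 29 adjusted over the list alone (camera adjusted p = 2.3e-17, and adjusted p = 0.377 with an estimated correlation).

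Myf5 gave 527 higher and 316 lower genes of 13825 by edgeR against the 5 GFP libraries. Against 1x GFP 142 were higher and 21 lower, of which 105 and 11 were shared, and the 6 deeper libraries alone gave 0 calls by edgeR, with 1212 at an unadjusted p under 0.05. The total of 843 moved to between 246 and 378 without any 1 of the MOI libraries, to 293 without 1x Myf5, to 57 without 2x Myf5 and to 5063 without 1x GFP. With a dose term for the 1x and 2x libraries it was 1352.

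**Figure D2:**
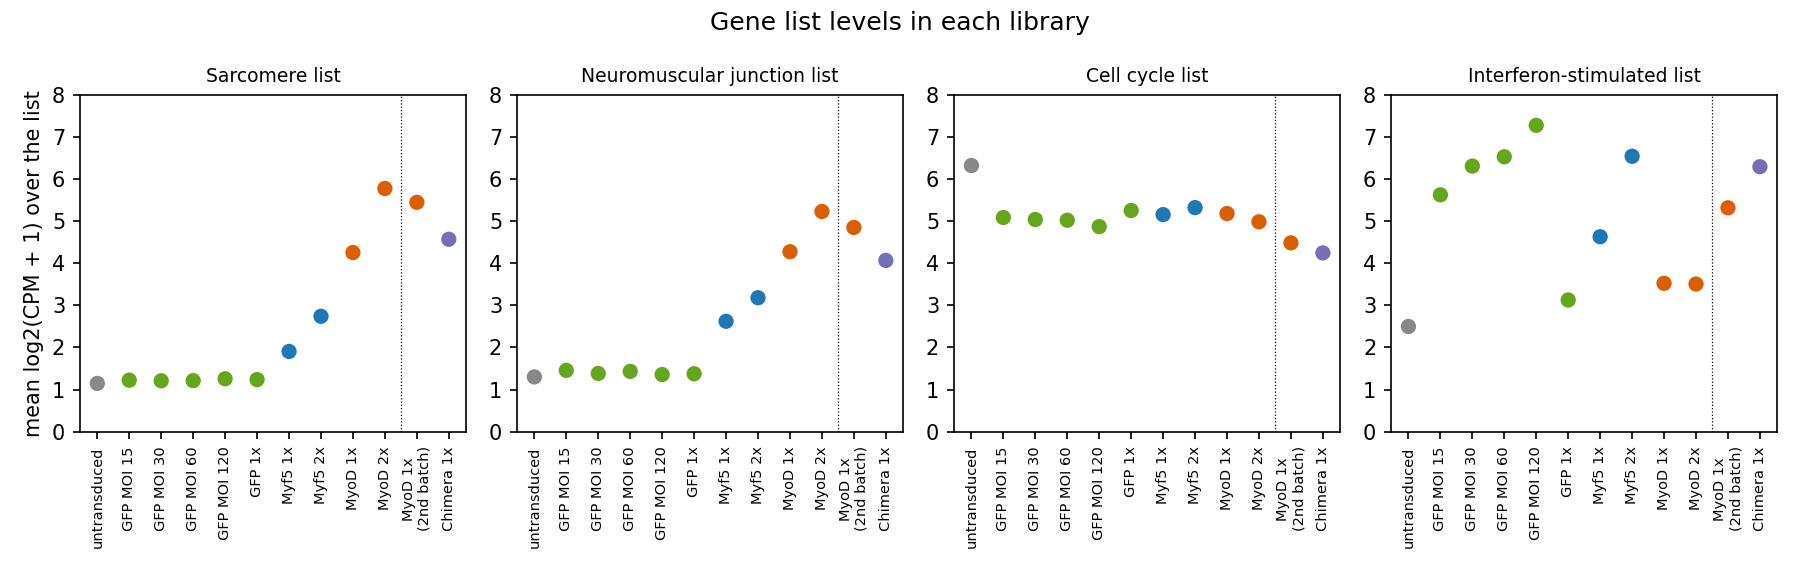
Mean log2(CPM + 1) of 4 gene lists in each of the 12 libraries, 1 point per library, with a dotted line between the separately made tables. The sarcomere score runs from 1.15 without virus to 5.78 in 2x MyoD, the cell cycle score is highest without virus at 6.32, and the interferon score runs from 2.50 without virus to 7.28 at an MOI of 120.

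MyoD against Myf5 compared both factors directly, with no control library in the contrast. Contractile genes were higher with MyoD: 24 of 29 sarcomere genes were called (29 adjusted over the list alone). Only 12 of these 29, and 10 of the 20 neuromuscular genes, reached the filter in the GFP libraries. The MyoD libraries alone can meet that filter, which favours genes higher with MyoD in these lists. They included the slow troponin Tnni1 at 5.99 ± 0.81, the embryonic myosin Myh3 at 5.29 ± 0.95, Actc1 at 5.09 ± 0.86, the fast troponin Tnnc2 at 4.93 ± 0.59 and Tnnt2 at 4.83 ± 0.73. In the neuromuscular list 13 of 20 were higher (18 adjusted over the list alone), among them the sarcoglycan Sgca (4.25 ± 0.43), while Chrng differed by 1.36 and Rapsn by 1.28. Myog (4.90 ± 0.89), Rbm24 (4.31 ± 0.67) and Mef2a (1.63 ± 0.23) were among 9 of 16 transcription factor and cofactor genes higher with MyoD, and adjusted over the list alone 12 were higher and 1 lower. Of the energy genes 5 of 13 were higher, among them Cox8b (2.53 ± 0.43) and Cox7a1 (1.47 ± 0.22), or 6 adjusted over the list alone. Outside the lists Myo5b, a myosin motor gene, was higher by 4.78 ± 0.65.

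Among genes called lower with MyoD than with Myf5, the largest differences after Myf5 itself (-3.87 ± 0.23) were in Saa3 (-1.52 ± 0.25), Cp (-1.45 ± 0.22), Lcn2 (-1.39 ± 0.26), Casp4 (-1.31 ± 0.28), Ifitm3 (-1.31 ± 0.31) and Ly6c1 (-1.30 ± 0.26). Lox (-1.22 ± 0.22) followed and was the 1 matrix gene of 28 called on either scale in the main fit. Once the MOI libraries formed a group of their own, more matrix genes were called lower with MyoD, Pdgfra (-0.84) among them, and none higher. Notch1 (1.95 ± 0.21), Hes1 (1.18 ± 0.21) and 3 other genes of the 11 in the Notch and Id list were higher with MyoD, or 6 adjusted over the list alone. Of 9 smooth muscle genes Ckb (2.28 ± 0.34) was higher, or 2 adjusted over the list alone. The interferon-stimulated list had a median of -2.60 with no member called by edgeR, as for Ifit2 (-1.73 ± 0.61) and Gbp2 (-2.05 ± 0.74), and 25 of 30 members were lower with MyoD once the MOI libraries formed a group of their own.

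By camera, the sarcomere list differed at an adjusted p of 1.05e-19 (median 3.71), the neuromuscular list at 3.0e-12 (2.54), the energy list at 9.6e-06 (1.38) and the Notch list at 0.00158 (0.31), each with adjusted p = 0.247 with an estimated correlation. The transcription factors had 2.9e-06 (0.72, and adjusted p = 0.274 with an estimated correlation) and the interferon list 8.35e-06 (adjusted p = 0.53 with an estimated correlation). The matrix list had 7.4e-05 (-0.26, and adjusted p = 0.395 with an estimated correlation) and the smooth muscle list 0.0324 (0.78, and adjusted p = 0.395 with an estimated correlation). Lower medians with MyoD, with no member called by edgeR in the main fit, stood behind the calls of the cell cycle list at 0.0347 (-0.23, and adjusted p = 0.693 with an estimated correlation) and the stress list at 0.032 (-0.18, and adjusted p = 0.32 with an estimated correlation). Once the MOI libraries formed a group of their own, edgeR called members of both lists, the cell cycle genes in either direction.

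In all, 582 genes were higher and 179 lower with MyoD than with Myf5. With the MOI libraries as a group of their own, which narrows the pooled spread, these became 1474 and 1208, with 581 and 179 in common, and the 6 deeper libraries alone gave 0 by edgeR, with 3115 at an unadjusted p under 0.05. The total of 761 moved to 2100 without 1x MyoD, 17 without 2x MyoD, 2 without 1x Myf5 and 2 without 2x Myf5. With a dose term that pairs the 1x and the 2x libraries of both factors it was 1400.

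The overlap of both responses was measured next. Of 13825 genes, 488 rose with both factors, where lists drawn independently would share 112.8. In turn 294 fell with both, where they would share 66.2, and none was called in opposite directions with all 5 GFP libraries as controls. With the 4 MOI libraries alone as controls 22 were, 7 of them higher with MyoD and lower with Myf5 and 15 the reverse. Of the 488, 129 were higher with MyoD than with Myf5 by the direct test, 1 was lower and 358 were not called different, although 406 had the higher value with MyoD. Among list genes that MyoD raised at least 2-fold, the median gene reached 44.8% of its MyoD log2 response with Myf5 in the sarcomere list (27 genes), 51.6% in the neuromuscular list (18 genes) and 65.7% in the fusion list (5 genes). Another 39 genes rose with Myf5 only, and 7 of them were lower with MyoD by the direct test.

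Across genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of 0.862 and a covariance of 0.507. Both comparisons share the GFP libraries. Unchanged groups simulated around the GFP mean (40 draws) gave an r of 0.331, a covariance of 0.0192 and 0 shared calls. Unchanged groups placed around the 1x GFP library with the real GFP libraries kept gave an r of 0.917, a covariance of 0.255 and 0 shared calls. Because this r without any response lay above the observed 0.862, the correlation decides nothing about a shared response. Around the GFP mean a mean of 0.125 genes was called higher with MyoD and 0.05 with Myf5, and around 1x GFP 0 with either. Without calls none can be shared, so the 0 shared calls decide nothing about overlap. With the GFP libraries split between the comparisons, 135 genes rose with both (22.5 if independent) and 21 fell with both (3.01 if independent). The r was then 0.870 and the covariance 0.541. Each part of that split held MOI libraries, so a shift of the MOI set stayed in both comparisons. Against 1x GFP alone 136 rose with both and 19 fell with both, with an r of 0.812.

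**Figure D3:**
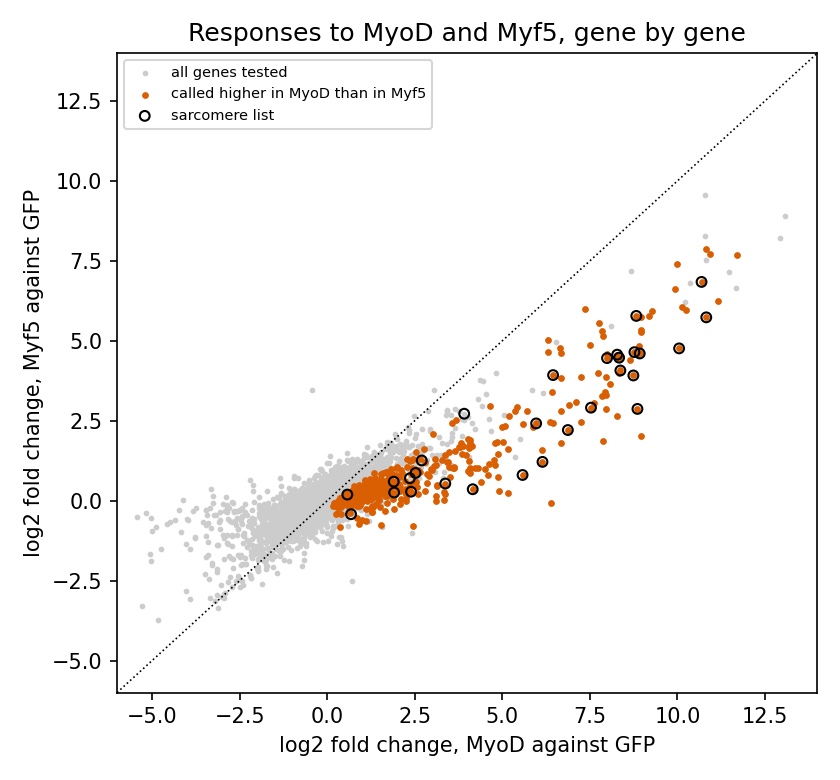
Log2 fold change against the 5 GFP libraries with MyoD (horizontal axis) and with Myf5 (vertical axis), 1 point per gene for 13825 genes, with a dotted line of equal response. Orange points are the 582 genes called higher with MyoD than with Myf5, and circles mark the 29 sarcomere genes, all of which lie under the line.

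The untransduced library was compared with the GFP libraries. It is 1 library, so an effect of the virus cannot be told apart from the state of that library. Cell cycle genes were higher without virus in 32 of 34 cases (34 adjusted over the list alone), with the thymidine kinase Tk1 at 2.25 ± 0.30, while Mcm6 (0.56) and Cdt1 (1.04) did not pass over all genes. The cell cycle repressors E2f7 (2.19 ± 0.30) and E2f8 (2.06 ± 0.36), the DNA repair gene Fignl1 (2.04 ± 0.21) and the peptide hormone gene Adm (2.13 ± 0.42) were the other largest rises. Lower without virus were the acute-phase gene Lcn2 (-2.85 ± 0.36), the complement gene C3 (-2.06 ± 0.23), Ehf (-3.79 ± 0.58), Steap4 (-2.64 ± 0.69) and Acpp (-2.08 ± 0.48). In the interferon-stimulated list the median was -4.83, with no member called over all genes and 28 of 30 lower adjusted over the list alone. The stress list had 5 of 17 genes lower (7 lower and 1 higher adjusted over the list alone), led by Trib3 (-1.85) and Ddit3 (-1.29).

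The cell cycle list stood higher by camera (adjusted p = 9.15e-27, median 1.34, and adjusted p = 0.457 with an estimated correlation) and the interferon list lower (7.6e-09, and adjusted p = 0.939 with an estimated correlation). In all 806 genes were higher and 348 lower without virus, a contrast in which the 1 untransduced library was assumed to vary like the other groups. Against the 1x GFP library 466 were higher and 217 lower, of which 393 and 96 were shared. There 30 of 34 cell cycle genes were higher (median 1.11), Tk1 was at 1.62 and Lcn2 at -3.12, and E2f8, Steap4 and Acpp were not called. The interferon median was -1.13. The 6 deeper libraries alone gave 0 calls by edgeR, with 1655 at an unadjusted p under 0.05. The total of 1154 moved to 593, 540, 535 and 717 without the libraries at an MOI of 15, 30, 60 and 120, and to 5142 without 1x GFP.

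The MOI series tested whether GFP virus alone acts by dose. All 30 interferon-stimulated genes rose with MOI, also when adjusted over the list alone, by a median log2 of 0.48 for every 2-fold increase in MOI, with the antiviral gene Rsad2 at 1.01 ± 0.08. The interferon-inducible Ifi206 (1.02 ± 0.07) and Oas1g (1.01 ± 0.06) were also among the largest slopes, together with Tgtp1 (0.97 ± 0.07) and Tgtp2 (0.97 ± 0.07), near-identical copies whose counts are uncertain. All 17 cholesterol synthesis genes fell, also when adjusted over the list alone, by a median log2 of -0.14 on the same scale. Of 17 p53 targets 10 rose (12 adjusted over the list alone), including Mdm2 (0.15) and Cdkn1a (0.09), and of 34 cell cycle genes 13 fell and 1 rose (16 and 2 adjusted over the list alone). The largest falls were Tubb3 (-0.29 ± 0.05), Trib3 (-0.28 ± 0.03), Slc2a6 (-0.28 ± 0.04), Stra6 (-0.27 ± 0.04) and Uchl1 (-0.25 ± 0.04).

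By camera the interferon list had an adjusted p of 1.0e-29, cholesterol synthesis 1.5e-12, cell cycle 2.9e-06 (median -0.09), p53 targets 3.5e-06 (0.08) and the macrophage list of 3 genes 0.013 (-0.15, no member called over all genes and 2 lower adjusted over the list alone). For each of these 5 lists camera gave adjusted p = 0.647 with an estimated correlation. Fry called none of them, with adjusted p of 0.0885, 0.109, 0.118, 0.0706 and 0.109 in that order. The 2 lists that fry called were smooth muscle and stress (adjusted p = 0.0249 by fry for each), which preset camera did not call. Of 13383 genes 544 rose and 458 fell with MOI (edgeR, 2 residual degrees of freedom). With the untransduced library added as dose 0, edgeR called 0 genes, with 3601 at an unadjusted p under 0.05, and Trib3 (0.20) and Stra6 (0.19) turned positive, uncalled. The total was 529 without the library at an MOI of 15, 1552 without that at 60 and 338 without that at 120.

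The 2x against 1x comparison estimated 1 dose effect shared by MyoD and Myf5. Over all genes 3 were called, the sarcomere genes Ttn (2.14 ± 0.12), Tnnt2 (1.92 ± 0.14) and Acta1, the skeletal actin (1.88 ± 0.11). No gene was called by edgeR without 1x MyoD (307 at an unadjusted p under 0.05) or without 2x MyoD (300), and 6 and 5 were called without 1x Myf5 and 2x Myf5. Adjusted over the list alone, 25 of 29 sarcomere genes and 14 of 20 neuromuscular genes were higher at 2x, with medians of 1.59 and 0.98. The 2x libraries alone can meet the count filter, which can favour rises with dose in these lists. Both lists were also past camera with an estimated correlation (adjusted p = 8.6e-23 and 8.0e-10 with the preset value, and adjusted p = 0.0276 with an estimated correlation for each). With the MOI libraries as their own group the sarcomere list had adjusted p = 0.0666 with an estimated correlation and the neuromuscular list adjusted p = 0.0753 with an estimated correlation, so both calls were lost. Adjusted over the list alone, 5 of 13 energy genes and 9 of 16 transcription factor genes were higher and 7 of 28 matrix genes lower, with camera adjusted p of 9.6e-05 (median 0.43), 2.3e-07 (0.46) and 8.0e-10 (-0.32). These 3 lists each had adjusted p = 0.069 with an estimated correlation. No gene was lower at 2x over all 13825 genes by edgeR, with 1528 at an unadjusted p under 0.05 in either direction, and DESeq2 called 104 lower and limma-voom 22.

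The interferon list's median was 1.00 with no member called (camera adjusted p = 0.0336, and adjusted p = 0.875 with an estimated correlation), and its score was 4.63 in 1x Myf5, 6.54 in 2x Myf5, 3.53 in 1x MyoD and 3.51 in 2x MyoD. The serum response list (median -0.24, camera adjusted p = 0.0133, and adjusted p = 0.612 with an estimated correlation), the neuron and glia list (-0.30, 0.046, and adjusted p = 0.292 with an estimated correlation, but 0.113 by preset camera with the MOI libraries apart) and the chondrocyte list (-0.34, 0.00299, and adjusted p = 0.0697 with an estimated correlation) lay lower, with 0, 0 and 2 members lower adjusted over the list alone. With the MOI libraries as their own group 557 genes were higher and 462 lower, and the 6 deeper libraries alone gave 62 and 5.

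Chimera was compared with second-batch MyoD, 1 library each, so that the differences have no replicate check. Intervals of single-gene ratios cover counting error only, and intervals of list medians measure the spread between genes, not between libraries. Among genes higher with MyoD than with Myf5 in the first table, Myog had 0.426 times the second-batch MyoD level (95% interval 0.414 to 0.438), Actc1 0.259 (0.251 to 0.269), Tnni1 0.277 (0.261 to 0.294), Tnnt2 0.314 (0.305 to 0.323) and Rbm24 0.252 (0.222 to 0.284), but Mef2a 0.888 (0.860 to 0.916). Higher with Chimera were Ogn, a small proteoglycan, at 10.4 (9.73 to 11.1), Lox at 3.02 (2.93 to 3.10), Pdgfra at 2.03 (1.98 to 2.09), Ldb2 at 12.6 (10.0 to 16.1) and Smoc2 at 12.4 (10.4 to 14.9). Myf5 reads were 11.2 times as abundant (10.1 to 12.6) and Myod1 reads 0.0681 times (0.0624 to 0.0742). The interferon-inducible Oas1g (11.1, interval 7.62 to 16.7), Oas1a (10.8, 8.05 to 14.7) and Sp100 (10.96, 7.15 to 17.6) were higher, as were Arhgap20 (10.5), Clca3a1 (10.2) and Fbn2 (9.79). The acute-phase genes Saa3 (2.13) and Cp (4.35) were higher, and Lcn2 (0.833, interval 0.667 to 1.04) was within counting error. Besides Myod1, the lowest ratios included those of Rspo4 (1 against 49 counts, ratio 0.0193, 0.000478 to 0.112), Shisal1 (0.0864), Nespas (0.0913), Gm15512 (0.0976), Arhgap22 (0.107), Kcnc1 (0.108), Asb2 (0.109) and Slc6a13 (0.126). Nespas is an antisense transcript, and without stated strand its reads cannot be told apart from those of its partner.

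Of 13412 genes with at least 50 counts over both libraries, 182 were more than 2-fold higher and 134 more than 2-fold lower with Chimera by the bounds of their intervals, and the median log2 ratio of all was -0.02. Genes of a list can move together, whereas random lists draw unrelated genes. A place beyond all random lists is therefore descriptive and can come from 1 difference between the libraries. Against second-batch MyoD the sarcomere list had a median log2 ratio of -0.95, below all 10000 random lists of the same size and expression, with 25 of 29 genes lower and none higher by their intervals. The neuromuscular list was at -0.85 (17 of 20 lower), also below all random lists. The interferon list was at 0.98 (26 of 30 higher) and above all random lists, and the matrix list was at 0.38 (19 of 28 higher and 7 lower, percentile 99.99). Cholesterol synthesis was at -1.01 with all 17 genes lower, and the serum response list was at -0.51 (13 of 18 lower and 5 higher). These 2 lists lay below all random lists, although the interval of the serum response median, -0.81 to 0.27, held 0. The energy list (-0.45, percentile 0.07) and the cell cycle list (-0.29, percentile 0.01) lay low as well. Transcription factors (-0.11), fusion genes (0.08), the Notch and Id list (0.11), p53 targets (0.01), the stress list (-0.02) and smooth muscle genes (0.17) lay between percentiles 13.3 and 92.2. With the first-batch 1x MyoD library of the other table as reference, the sarcomere median turned to 0.45 (0.15 to 0.64), above all random lists. Neuromuscular genes were then at -0.28 (percentile 0.32), energy genes at -0.11 (17.9) and serum response genes at -0.015 (35.4). The interferon (3.18), matrix (0.56), cholesterol (-1.42) and cell cycle (-1.02) lists lay beyond all random lists on the side they had before.

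**Figure D4:**
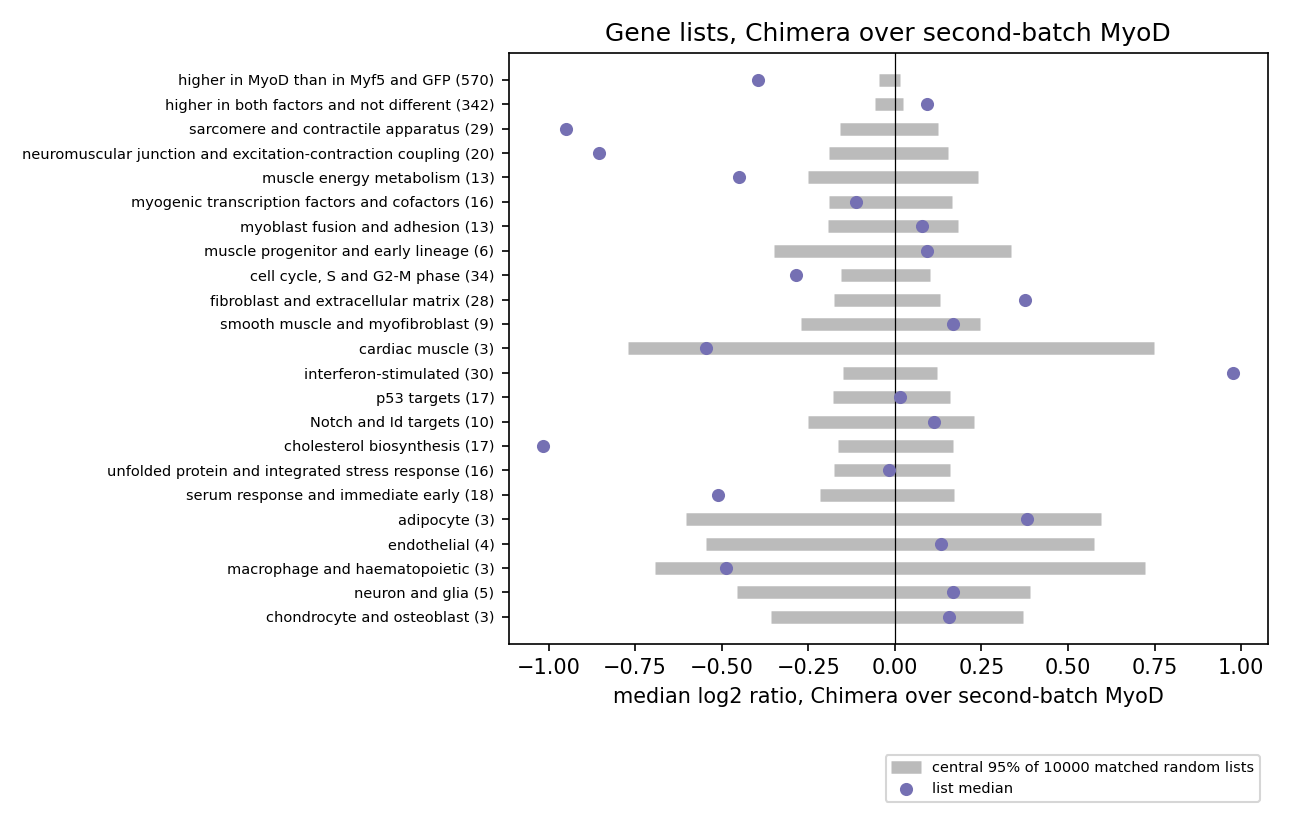
Median log2 ratio of Chimera over second-batch MyoD for each gene list (points, with the number of genes) against the central 95% of 10000 random lists matched on size and expression (grey bars). The interferon list lies at 0.98 above its bar, and the sarcomere list at -0.95 and cholesterol synthesis at -1.01 lie below theirs.

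Chimera was then read in the genes that separated MyoD from Myf5 in the first table. With second-batch MyoD as reference, the libraries read differ from those that defined the lists. The 570 measured genes that were higher with MyoD than with both Myf5 and GFP had a median log2 ratio of Chimera over second-batch MyoD of -0.40 (interval of the median -0.44 to -0.34), below all 10000 matched random lists. By their intervals 418 genes were lower and 65 higher. The 342 measured genes higher with both factors and not called different between them had a median of 0.09 (0.03 to 0.14), above all random lists. Limited to the 112 of these genes that changed at least 2-fold, the median was 0.026 (-0.083 to 0.19), at percentile 87.6 of the random lists. Of 749 genes called between MyoD and Myf5, 609 differed between Chimera and second-batch MyoD in the direction of Myf5, with a Spearman rho across genes of 0.648. With first-batch 1x MyoD as reference these were 458 genes and a rho of 0.106. The 570 genes also had a median log2 ratio of 0.50 for 2x over 1x MyoD. Across the tables, second-batch over first-batch MyoD gave them 0.28. A shift in the direction of Myf5 therefore cannot be told apart here from a lower level of the factor or a high reference. When the first-batch 1x MyoD library of the other table served as reference, the medians were -0.082 for the 570 genes and -0.21 for the 342 genes, so the direction in the latter depended on the reference. That library helped to choose all these genes, so values with it as reference are not independent of the choice. Choosing genes as high with MyoD by itself lowers these medians. The random lists also leave out that genes chosen in this way can move together.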

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

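The tests of the interferon-stimulated list against viral dose, of transgene level and of MyoD reads in the control libraries were chosen only after the results were seen. Within the GFP group, 25 measures were checked for 1 library far from the other 4, a check that chance alone trips in about 1 group in 20, and 6 were found. In 5 of them the 1x GFP library stood apart, with 81.5 M counts, 0.503 CPM of Myog, and mean log2(CPM + 1) scores of 4.38 for smooth muscle genes, 4.44 for serum response genes and 3.39 for endothelial genes. The sixth was the progenitor list, at 3.64 in the library at an MOI of 15. Mitochondrial genes, which the totals of the Chimera comparison include, took 4.05% of the Chimera and 4.18% of the second-batch MyoD counts, while the first table lists none of their counts, and no biological explanation was tested.

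The first pattern was the distance of the 4 MOI libraries from 1x GFP, in 3369 genes. Thinned to the smallest depth, 77.1% of these were still called with the same sign, short of the 80% set beforehand for ruling depth out. The median difference kept 98.9% of its size, but random thinning keeps a ratio on average whatever its cause. That value therefore decides nothing about depth. Transcript length and GC content explained 1.84% of the variance, against the bound of 10% set beforehand. In the interferon-stimulated list 27 of 27 called genes (100%) had a slope over MOI of the same sign as their difference. The rise of all 30 list genes with MOI had already fixed that value, so it decides nothing about viral dose. Outside that list 66.6% of 3270 genes did, with 328 past the trend test in the same direction and 33 in the opposite one, so dose and library set cannot be told apart there, because only 1 GFP library lies outside the MOI set.

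The second pattern was the smaller muscle response to Myf5. A lower level of Myf5 than of Myod1 transcript could contribute: all 29 sarcomere genes were lower in 2x Myf5 than in 1x MyoD, by a median log2 of 1.92 (lower bound 0.93), while the gap in transgene CPM would give 0.70. It stays open, because the shift would be 2.48 if 1 CPM of Myf5 stood for 2 times fewer molecules, and protein levels were not measured. Across 700 genes raised at least 2-fold by MyoD, those that rose most from 1x to 2x MyoD also differed most between the factors (Spearman rho 0.793, genes not being independent replicates). Both measures hold the 2x MyoD library, which raises this rho. With the difference at 1x alone, where the shared 1x MyoD library acts the other way, rho was 0.654, and the dose changes of MyoD and Myf5 had a rho of 0.453. Because the difference also followed the size of the MyoD response (rho 0.726), this does not separate a weaker factor from one that acts on other genes.

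The third pattern was muscle transcripts in libraries that received no muscle factor. Over 16 MyoD-induced genes with no count in the MOI libraries, the untransduced library held 36 counts, 18 of them Myog, in proportions that 1 share of 0.0476% of the MyoD level could give (Poisson chi-square per degree of freedom 0.794, with 10 genes at no count). The 1x GFP library held 107 counts, a share of 0.126%, with a chi-square per degree of freedom of 2.94, which neither met the bound for 1 share nor excluded it. A small carry-over of reads between libraries of that set is therefore a candidate explanation in the untransduced library, and low expression in the cells was not tested.

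For the change from 1x to 2x in MyoD minus that in Myf5, each of the 4 arms was 1 library and the spread came from the GFP libraries alone. Preset camera called 10 of 21 lists and fry none (lowest adjusted p = 0.514), with no single gene called by edgeR (275 at an unadjusted p under 0.05) and no list called with an estimated correlation. With the spread of a fit that sets the MOI libraries apart, 4 genes were called, all with the larger change in MyoD (1548 at an unadjusted p under 0.05). Among them were Myod1 itself (1.06), Lzts3 (1.30) and Gm14419 (3.70). The median difference, MyoD minus Myf5, was 0.20 for sarcomere, 0.14 for neuromuscular, 0.22 for energy, 0.13 for transcription factor, 0.45 for smooth muscle, -0.32 for progenitor, -0.38 for cell cycle, -0.18 for matrix, -1.92 for interferon-stimulated and -0.22 for stress genes.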

How the results depend on the processing

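Values from the 6 deeper libraries alone, from a fit with the MOI libraries as their own group, without mitochondrial genes and for Chimera lists against first-batch MyoD were chosen after seeing the data. In comparisons of groups within the 6 deeper libraries, the spread came only from 1x against 2x of MyoD and of Myf5. Dose therefore counted as spread there, so a lack of calls does not tell whether a response holds at like depth. The replicate numbers of MyoD and Myf5 follow their 1x and 2x doses, so the paired fit was a dose term in place of a replicate block. GFP shares only the 1x dose with them, and nothing in the labels says that libraries of 1 number share a culture or a day. For MyoD against GFP, 15 of 17 alternatives gave a count within 1.5 times the reported one. DESeq2 called 2143 genes for Myf5 against GFP, 1750 for MyoD against Myf5, 2512 without virus, 486 along MOI and 290 for dose, and limma-voom 559 for Myf5 against GFP and 187 for dose. With the dose term, Myf5 against GFP gave 1352, MyoD against Myf5 1400 and MyoD against GFP 5812. For Myf5 against GFP, the MOI libraries as controls gave 5067, 1x GFP alone 163 and the untransduced library as an added control 459. With the MOI libraries as their own group the counts were 2682 for MyoD against Myf5, 683 without virus and 1019 for dose. The 6 deeper libraries alone, with fewer samples, gave 0 by edgeR for MyoD against GFP, Myf5 against GFP, MyoD against Myf5 and untransduced against GFP (4124, 1212, 3115 and 1655 at an unadjusted p under 0.05, no other tool being run on them) and 67 for dose. The dose count was 16 without a filter, and the MOI trend had 0 by edgeR with the untransduced library as dose 0 (3601 at an unadjusted p under 0.05), where Trib3 was at 0.20 and Stra6 at 0.19.

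Leaving out 1 library gave 1833 to 8073 genes for MyoD against GFP, 57 to 5063 for Myf5 against GFP, 2 to 2100 for MyoD against Myf5, 535 to 5142 without virus, 338 to 1552 along MOI and 0 to 6 for dose, a lone library being assumed to vary like the other groups. The cell cycle median for dose ranged from -0.22 to 0.18, positive without either MyoD library. Against 1x GFP, and in the 6 deeper libraries, list medians changed sign, among them, for MyoD, interferon 0.62 and 0.62 and cholesterol -0.041 and -0.043, with cell cycle at -0.27 in the deeper libraries. For Myf5 they were interferon 3.13 and 3.13, cell cycle -0.022 and -0.022 (-0.13 with the untransduced library added), serum response -0.37 and -0.37, and cholesterol -0.15 in the deeper libraries. Other medians turned against 1x GFP in lists that camera called with neither control. For MyoD these were cardiac (-0.24 to 0.084), progenitor (0.0063 to -0.13) and neuron (0.00032 to -0.23). For Myf5 they were endothelial (0.30 to -0.21), macrophage (0.18 to -0.25), adipocyte (0.15 to -0.070) and progenitor (-0.0074 to 0.18), and without virus the transcription factor, progenitor, Notch, endothelial, macrophage and chondrocyte lists did so. Without virus, the cholesterol median was -0.23 in the deeper libraries and -0.23 with the MOI libraries apart. Without a filter the macrophage median along MOI was 0.19. Over the 6 comparisons, preset camera called 49 lists, an estimated correlation 2 and fry 32. With the controls split, 135 genes rose with both factors. For genes higher with MyoD than with both Myf5 and GFP, the Chimera median was -0.71 in those changed at least 2-fold. It was -0.27 for the list from the fit with the MOI libraries apart and -0.082 against first-batch MyoD. With that reference, genes higher with both factors and not called different between them were at -0.21 and the sarcomere list at 0.45. The cause was not tested, except where fewer samples or another control define the setting. Leaving out the lowest MOI was part of leaving out each library. Depth limits genes near 1 CPM most in the MOI libraries, of 17.9 to 22.4 M counts.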

Other observations

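Interferon-stimulated and cholesterol synthesis genes moved apart along the MOI series and with Chimera, without a test of the opposition itself. Along the MOI series the former rose in 30 of 30 and the latter fell in 17 of 17 cases, and with Chimera over second-batch MyoD their median log2 ratios were 0.98 and -1.01. Without virus, both medians were lower than in 1x GFP, at -1.13 and -0.23. Their mean log2(CPM + 1) scores were 2.50 and 8.35 without virus, 3.13 and 8.58 in 1x GFP, 7.28 and 8.06 at an MOI of 120, 6.30 and 7.17 in Chimera and 5.32 and 8.24 in second-batch MyoD.

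The MOI libraries together, set against 1x GFP, had 27 of 30 interferon-stimulated genes higher (median 3.89), 11 cell cycle genes lower (-0.36), 11 serum response genes lower (-0.52) and 2 cholesterol genes lower (-0.32). These 4 lists passed preset camera, and had adjusted p = 0.578, 0.834, 0.578 and 0.843 with an estimated correlation. Vwf, the von Willebrand factor gene of endothelium, rose by 1.94 with MyoD and 2.10 with Myf5 against all GFP libraries, as did the neuronal cytoskeleton genes Map2 and Tubb3 (edgeR). Against 1x GFP the values for MyoD were 0.87 for Vwf and 0.67 for Map2, both called, and 0.50 for Tubb3, uncalled. Tubb3 also fell along the MOI series (-0.29), which lowers the control. Neither the endothelial nor the neuron and glia list passed camera. Against 1x GFP no gene of these lists rose with Myf5 by edgeR over all genes, and 1 of each did adjusted over the list alone.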
